A study of Nothobranchius furzeri with 20 samples.

How the data were processed

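RNA was measured in 20 liver libraries of male Nothobranchius furzeri of strain MZM-04/10p, 5 in each of 4 groups defined by the age and rotenone dose in the sample labels: 9 weeks at 0.1%, 1% or 10% of the LC50, and 27 weeks at 1%. Libraries were prepared from total RNA with the TruSeq RNA kit, per the labels' protocols. Replicate numbers were assigned in the order of the sample list and only name libraries; no label gave a batch, day or pairing.

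The authors deposited raw counts per gene, in a table of 15 libraries (9-week 1%, 9-week 10% and 27-week 1%) and a table of 5 libraries (9-week 0.1%). Per the submitters' processing notes, CASAVA 1.8.2, STAR 2.4.1d and featureCounts 1.4.6-p4 were used; their settings, the genome build, the annotation and any use of strand are not given in the sources used here. Counts of overlapping or antisense genes and of near-identical gene copies are therefore uncertain. Another 10 columns of the count tables belong to samples outside the sample list and were not used. The chi-square per degree of freedom between replicates lay between 54.8 and 540 over 40 pairs, so no library repeated another of its own group within sampling noise; pairs from different groups were not compared.

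The authors also deposited tables labelled RPKM, whose values were treated here as a score, since they were not scaled per library. The ratio of count to value between columns repeated every 35 rows: row classes of that period left 6.84e-08 of the variance of the log ratio of the first 2 columns, where the next best period left 0.823. The divisors recovered from this pattern equalled the totals of the 20 libraries to within a relative difference of 3.64e-06, which were recycled down the rows. Values were thereby scaled by between 0.682 and 1.47 times the correct factor. These tables served only as an alternative, tested with limma's trend method on log2(value + 0.1) or log2(value + 1) for genes with a mean value of 0.5 or more; fold changes on that scale understate changes of low genes. Gene lengths were recovered from them for 14584 genes.

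All 26739 gene identifiers have the form Nfu_g_1 and a number. None (0) matched the identifiers of the RefSeq gene table of assembly NfurGRZ-RIMD1, and the files do not pair them with names. The 38 gene lists fixed before the data were examined were therefore not tested, no gene is named or placed on a chromosome, and at most 2 identifiers that rose and 2 that fell are given per comparison. The rule, fixed before the data were examined for this case, took the largest log2 fold changes past the threshold among genes with a mean CPM of 1 or more in the groups compared; CPM were scaled by TMM factors.

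Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by group, TMM normalization, a quasi-likelihood fit with 1 mean per group, and two-sided F-tests with Benjamini-Hochberg adjustment within each comparison at 0.05. The comparisons of 10% with 1% and of 27 with 9 weeks used all 15 libraries of their table. Comparisons with the 0.1% group used all 20 libraries; since the table and the group coincide, no term for the table could be fitted. Standard errors of log2 fold changes were the absolute fold change divided by the square root of the F statistic. Contrasts of 1% with the other doses were added after the data were seen. Log2 CPM with a prior count of 2 served for principal components, rank correlations and correlations of fold changes. Comparisons sharing libraries were also set against 100 redraws of libraries' residuals without group effects, and their calls against lists shared by chance if independent and against 20 divisions of the shared 9-week 1% libraries (2 and 3 libraries, genes of the undivided fit). The overlaps with divided libraries were added after the data were seen. In 20 simulated data sets without group differences 0 genes were called, so these gave no value for shared calls.

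The test was tried on simulated counts with 200 changed genes. In the simulation of 10% against 1%, 17.9% of 2-fold and 68.2% of 4-fold changes were recovered among 16150 genes, with 0 false calls. The values were 17.9% and 72.7% for 27 against 9 weeks (16150 genes, 1 false call), 11.9% and 74.2% for 1% against 0.1% (16516 genes, 6 false calls), and 19.4% and 69.7% for 10% against 0.1% (16516 genes, 1 false call). For the added contrasts they were 28.4% and 77.3% (9-week 1%; 1 false call) and 46.3% and 92.4% (both 1% groups; 3 false calls). With only 200 changed genes the adjusted threshold is stricter than in comparisons with many calls, so these rates apply to comparisons with few changes. The simulated counts also gave a gene the same spread in all groups and held no deviating library. In the data the median standard deviation of a gene's log2 CPM was 0.64 at 9 weeks and 1% and 0.31 at 10%. The numbers of false calls therefore do not show error control in these data.

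Alternatives were DESeq2 1.42.0 size factors and its Wald test, limma 3.58.1 voom, other filters on low counts, other sets of libraries, a test against a fold change of 1.5, the deposited score tables and each library left out in turn. Counts of calls were compared with 100 divisions of the same libraries, the real one included. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.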

Results

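Livers of male turquoise killifish (Nothobranchius furzeri), a short-lived annual fish used in studies of ageing, were profiled by RNA sequencing after treatment with rotenone, an inhibitor of mitochondrial complex I. The fish were of the wild-derived strain MZM-04/10p. Doses were given as percentages of the LC50, the median lethal concentration. There were 4 groups of 5 libraries: 9-week fish at 0.1%, 1% and 10% of the LC50, and 27-week fish at 1%. No group was labelled as untreated, so each comparison was between doses or between ages at 1 dose. The design addresses how gene expression in the liver differs with rotenone dose in young fish and with age at the same nominal dose.

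Each library held between 23.5 M and 33.9 M counts (M, mega) assigned to genes, and between 18665 and 20292 genes had at least 1 count in a library. Depth overlapped between the groups, with medians of 25.5 M counts at 9 weeks and 1%, 27.9 M at 10%, 27.3 M at 0.1% and 25.0 M at 27 weeks and 1%. Replicates of the 10% group correlated with Spearman's rho across genes of 0.931 to 0.970, those of the 27-week group with 0.927 to 0.968, and those of the 0.1% group with 0.868 to 0.977. In the 9-week 1% group, 4 libraries correlated with each other at 0.932 to 0.962, while replicate 5 correlated with these at only 0.821 to 0.849. The median standard deviation of a gene's log2 CPM was accordingly 0.64 in the 9-week 1% group, 0.39 in it without replicate 5, 0.44 at 0.1%, 0.31 at 10% and 0.31 at 27 weeks. The labels do not state whether each library came from a separate fish, so p-values measure the spread between these libraries. The edgeR fit pooled each gene's spread over all groups in it, which may be too small for the 9-week 1% group.

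On principal component 1, with 19.4% of the variance of the 2000 most variable genes, all 5 libraries of the 9-week 1% group lay at -28.5 or below and all other 15 libraries lay at -19.0 or above. The 0.1%, 10% and 27-week 1% groups overlapped on this axis, with the 27-week libraries between -13.3 and 22.6. Component 2 carried 17.4% of the variance and spread libraries within groups, and component 3, with 16.1%, set replicate 5 of the 9-week 1% group at -69.0, apart from all other libraries.

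**Figure D1:**
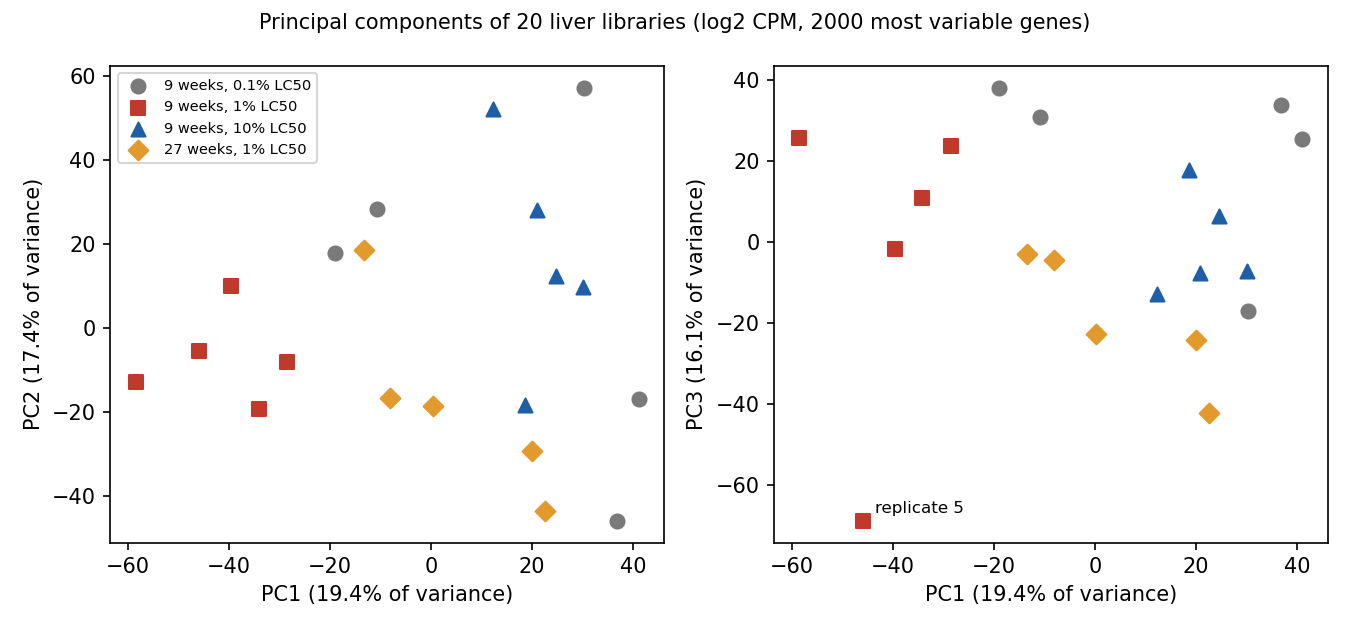
Principal component scores of the 20 liver libraries, with component 1 (19.4% of variance) on the x axis of both panels and component 2 (17.4%) or 3 (16.1%) on the y axis; each point is a library, coloured by age and dose. The 5 libraries of the 9-week 1% group lie at the left of all others, and its replicate 5 lies alone at the bottom of the right panel.

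The livers of 9-week fish at 10% of the LC50 differed from those at 1% in 3713 of 16150 genes tested, of which 1528 were higher and 2185 lower at 10%. Of these, 2252 differed by 2-fold or more. The genes that rose held 5.43% ± 0.21 of all counts at 10% and 2.45% ± 0.66 at 1% (SD, n = 5 each), and the genes that fell held 4.43% ± 0.34 at 10% and 9.88% ± 1.45 at 1%. Nfu_g_1_001720 fell from 23.2 ± 12.7 CPM at 1% to 0.442 ± 0.132 CPM at 10% (SD, n = 5 each), a log2 change of -5.71 ± 0.54 (SE; edgeR adjusted p = 3.37e-05), and was lower in 5 of 5 libraries than in any library at 1%. In the 27-week 1% group the same gene stood at 26.2 ± 15.7 CPM. Nfu_g_1_007386 was at 492 ± 355 CPM at 1% and at 4.90 ± 3.21 CPM at 10%, a log2 change of -6.65 ± 1.05 (SE; edgeR adjusted p = 0.000486). Replicate 3 of the 1% group held only 4.59 CPM of it, so that 3 of the 5 libraries at 10% lay below all at 1%. Nfu_g_1_020445 rose from 0.158 ± 0.276 to 8.55 ± 9.34 CPM, with a log2 change of 6.03 ± 1.70 (SE; edgeR adjusted p = 0.0189), and was higher in 4 of 5 libraries. Nfu_g_1_005235 rose from 0.0486 ± 0.0429 to 2.05 ± 2.13 CPM, with a log2 change of 5.40 ± 1.33 (SE; edgeR adjusted p = 0.00919), also in 4 of 5 libraries. Some libraries held no count of the last 2 genes, so their fitted folds depend on the prior count, and limma voom did not call them (log2 changes 4.92 and 4.18; adjusted p = 0.221 and 0.125). The log2 change of Nfu_g_1_020445 was 7.80 without replicate 5 at 1%, and that of Nfu_g_1_007386 was -5.67 with limma voom. Nfu_g_1_020445 also missed the threshold on the authors' RPKM-labelled score with a pseudocount of 0.1 (limma adjusted p = 0.0778; 0.0801 after rescaling) but passed with a pseudocount of 1 (0.0378). On that score 1747 and 1763 genes passed with these pseudocounts, and 2808 after rescaling to each library's own total. With the other group of the same table left out of the fit, 2453 genes passed.

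Against the lowest dose, 9-week livers at 1% differed from those at 0.1% in 3204 of 16516 genes, with 1912 higher and 1292 lower at 1%. The genes that rose held 9.30% ± 1.48 of counts at 1% and 3.81% ± 0.72 at 0.1% (SD, n = 5 each), and those that fell held 3.25% ± 1.06 and 8.27% ± 2.31. Nfu_g_1_018107 was at 14.7 ± 9.3 CPM at 1% and 0.220 ± 0.123 CPM at 0.1%, a log2 change of 6.07 ± 0.72 (SE; edgeR adjusted p = 2.77e-05), and was higher in 5 of 5 libraries. Nfu_g_1_007386 was at 496 ± 362 CPM at 1% on the scale of all 20 libraries and at 3.18 ± 2.26 CPM at 0.1%, a log2 change of 7.28 ± 1.05 (SE; edgeR adjusted p = 0.000132), and was higher in 4 of 5 libraries. Nfu_g_1_021966 fell from 2.36 ± 3.62 CPM at 0.1% to 0.0212 ± 0.0312 CPM at 1%, with a log2 change of -6.49 ± 1.53 (SE; edgeR adjusted p = 0.00544), and was lower in 4 of 5 libraries. Its log2 change was -4.99 without replicate 1 at 0.1%, which held 8.53 CPM, and -7.42 without replicate 3 at 1%. It was not called by limma voom (log2 change -4.26; adjusted p = 0.0858). Nfu_g_1_020445, which was higher at 10% than at 1%, also had a higher mean at 0.1% than at 1% (10.7 ± 15.35 against 0.162 ± 0.285 CPM). Its log2 change was -6.35 ± 2.05 (SE; edgeR adjusted p = 0.0350), but 0 of 5 libraries at 1% lay below all at 0.1%. It did not pass without any one of replicates 1 to 4 at 1% (log2 changes -5.93, -6.05, -6.08 and -6.30) or replicates 1 and 5 at 0.1% (-5.30 and -5.99), with adjusted p between 0.0659 and 0.0794. Without replicate 5 at 1% the log2 change was -8.17. It was not called by limma voom (log2 change -3.71; adjusted p = 0.478), by which the log2 change of Nfu_g_1_007386 was 6.45. The 0.1% libraries were deposited in their own table, so no term for the table could be fitted. With only both groups in the fit 1091 genes passed.

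The 0.1% and 10% groups, the farthest apart in dose, differed in 8 of the same 16516 genes by edgeR, with 3 higher and 5 lower at 10%. Unadjusted p was below 0.05 for 1079 genes, or 6.53% of those tested, and DESeq2 called 144 genes and limma voom 5. Nfu_g_1_006676 rose from 23.25 ± 7.53 CPM at 0.1% to 104 ± 30 CPM at 10% (SD, n = 5 each), a log2 change of 2.16 ± 0.26 (SE; edgeR adjusted p = 0.00153), and stood at 16.0 ± 5.5 CPM at 1%. Nfu_g_1_021302 rose from 0.685 ± 0.340 to 5.00 ± 3.33 CPM, with a log2 change of 2.86 ± 0.45 (SE; edgeR adjusted p = 0.0123). Nfu_g_1_007647 fell from 649 ± 651 to 33.5 ± 18.32 CPM, with a log2 change of -4.28 ± 0.65 (SE; edgeR adjusted p = 0.00895), and Nfu_g_1_012912 fell from 44.2 ± 38.4 to 6.11 ± 1.68 CPM, with a log2 change of -2.85 ± 0.51 (SE; edgeR adjusted p = 0.0451). The log2 change of Nfu_g_1_007647 was -3.52 without replicate 1 at 0.1%. At 0.1%, Nfu_g_1_012912 stood at 96.2 and 74.3 CPM in replicates 1 and 5 and at 13.9 to 20.4 CPM in the others. Nfu_g_1_007647 was also highest in replicates 1 and 5 at 0.1%. For each of the 4 genes, 5 of 5 libraries at 10% lay outside the range at 0.1%. With only both groups fitted, edgeR lost Nfu_g_1_021302 (adjusted p = 0.136), Nfu_g_1_007647 (0.117) and Nfu_g_1_012912 (0.170), and limma voom lost Nfu_g_1_021302 (0.0748) and Nfu_g_1_012912 (0.178). The calls of Nfu_g_1_021302 (without replicate 1 or 4 at 10%, or 1 or 5 at 0.1%; adjusted p 0.0591 to 0.0654), Nfu_g_1_007647 (without replicate 1 or 4 at 10%; 0.0591) and Nfu_g_1_012912 (without any replicate at 10%, or 1 or 5 at 0.1%; 0.0960 to 0.190) ended with 1 library left out. The count itself moved to 37, 26 and 22 without replicates 2, 3 and 4 at 0.1%, to 4 without its replicate 1 or 5, to 3 without replicate 1 or 4 at 10%, to 5 without its replicate 3 or 5, and to 23 without replicate 5 of the 9-week 1% group. Genes higher at 10% were the majority without replicate 1, 3, 4 or 5 at 10% (66.7%, 60.0%, 66.7% and 60.0%, against 37.5%), so the calls gave no stable balance of directions.

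**Figure D2:**
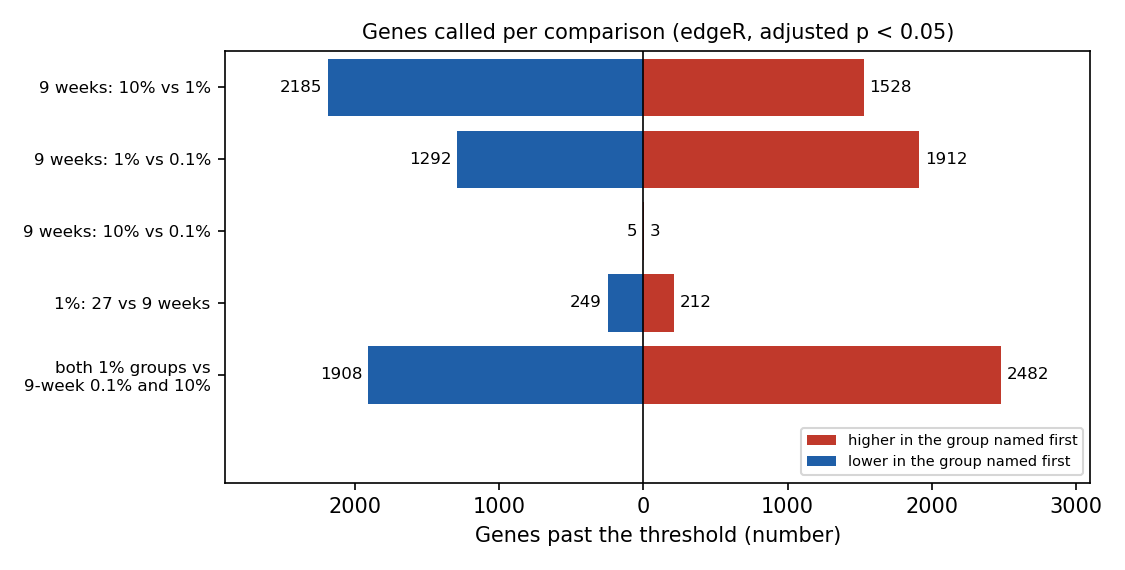
Number of genes past the threshold (x axis) in each comparison (y axis), with genes higher in the group named first to the right and genes lower in it to the left. The comparison of 10% with 0.1% gave 3 higher and 5 lower genes, against 1528 and 2185 for 10% with 1% and 1912 and 1292 for 1% with 0.1%.

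The genes that separated 1% from its neighbouring doses overlapped, and those shared moved almost only in opposite directions along the dose axis. Of the genes tested in both, 881 rose from 1% to 10% and fell from 0.1% to 1%, where independent lists would share 119, and 1560 moved the other way, where independent lists would share 258. Only 2 genes fell at both steps and 0 rose at both, although independent lists would share 170 and 181. Since the 1% group enters with opposite signs, part of this deficit is built in. Both comparisons contain the 9-week 1% libraries. With these divided between the comparisons in 20 ways, a median of 297 genes (138 to 388) rose from 1% to 10% and fell from 0.1% to 1%, where independent lists would share 32.1. A median of 800 (316 to 897) moved the other way, where independent lists would share 149. The lists then held medians of 2685 and 2284.5 genes. Medians of 2 genes (0 to 53) fell and 1 (0 to 28) rose at both steps, where independent lists would share 75.6 and 60.1. In 20 simulations with no group differences 0 genes were called, so these give no value for sharing by chance. Across genes, the fold changes of 10% and of 0.1% against 1% correlated with r = 0.839, where simulated groups without effects gave a mean r of 0.464 (range -0.289 to 0.928); the covariance was 0.570 against 0.108 in the simulations. The undivided r lay within the simulated range. With the 1% libraries divided between both comparisons, the mean r was 0.506 over 20 divisions (0.242 to 0.654), and genes are not independent replicates. In a contrast added after the data were seen, 9-week livers at 1% differed from the mean of 0.1% and 10% in 4484 genes, 2722 higher and 1762 lower at 1%.

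At 1% of the LC50, 27-week livers differed from 9-week livers in 461 of 16150 genes, of which 212 were higher and 249 lower at 27 weeks, a balance that did not hold across settings. The genes that rose held 2.08% ± 0.45 of counts at 27 weeks and 0.456% ± 0.134 at 9 weeks (SD, n = 5 each), and those that fell held 2.93% ± 0.44 and 5.70% ± 0.70. Nfu_g_1_007386, high in most 9-week 1% libraries, stood at 2.41 ± 1.98 CPM at 27 weeks, a log2 change of -7.68 ± 1.10 (SE; edgeR adjusted p = 0.00538), with 4 of 5 libraries lower than all at 9 weeks. Nfu_g_1_021642 fell from 5.10 ± 5.04 to 0.0475 ± 0.0450 CPM, with a log2 change of -6.74 ± 1.39 (SE; edgeR adjusted p = 0.0254), but only 1 of 5 libraries lay below all at 9 weeks, and it did not pass without replicate 2, 3 or 5 at 27 weeks (adjusted p 0.0539 to 0.0754). Its log2 change was -6.07 without replicate 2 at 9 weeks and -7.39 without replicate 1 at 27 weeks. The largest fitted rises, of Nfu_g_1_014761 (log2 change 7.64 ± 1.98, SE; edgeR adjusted p = 0.0499) and Nfu_g_1_022891 (7.60 ± 1.75; adjusted p = 0.0366), came mostly from replicate 3 at 27 weeks, which held 378 and 172 CPM. Their means were 78.5 ± 167 and 36.3 ± 76.0 CPM at 27 weeks against 0.379 ± 0.327 and 0.194 ± 0.228 CPM at 9 weeks, and 2 and 3 of the 5 libraries lay above all at 9 weeks. Without that replicate their log2 changes were 3.25 (adjusted p = 0.191) and 3.62 (0.0979) by edgeR. The call of Nfu_g_1_014761 also ended without replicate 2 at 27 weeks or any of replicates 1 to 5 at 9 weeks (adjusted p 0.0634 to 0.0876). That of Nfu_g_1_022891 ended without replicate 2 at 27 weeks or any of replicates 1 to 4 at 9 weeks (0.0515 to 0.0639). Of the named genes limma voom called only Nfu_g_1_007386 (log2 change -6.91). It gave 2.99 for Nfu_g_1_014761 (adjusted p = 0.491), 4.40 for Nfu_g_1_022891 (0.299) and -5.18 for Nfu_g_1_021642 (0.173). The count was sensitive to the libraries in the fit: it was 62, 46, 241, 240 and 200 without replicates 2, 3, 1, 4 and 5 at 27 weeks, 254 without replicate 2 at 9 weeks and 25 with only both groups fitted, while DESeq2 called 1785 genes and limma voom 225. Of the calls, 46.0% were higher at 27 weeks in the full fit. The share was 66.4%, 66.1%, 69.6%, 57.5% and 72.5% without replicates 1 to 5 at 27 weeks, 34.03%, 33.91% and 50.3% without replicates 3, 4 and 5 at 9 weeks, 54.7% with limma voom and 84.0% with only both groups fitted. With no untreated fish of either age, a change with age cannot be told apart from an age-dependent response to rotenone.

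The 27-week 1% livers shared with the 9-week 1% livers a set of differences from the other doses. The mean distance of 27-week libraries (root mean square of log2 CPM differences) was 1.16 to 9-week 1%, 1.03 to 10% and 1.11 to 0.1%. This distance includes the spread within each group. The 9-week 1% libraries lay 1.21 apart among themselves, against 0.747 at 10% and 1.05 at 0.1%. The distances therefore do not tell which group was nearest to the 27-week group. With all 20 libraries in the fit, the 27-week group differed from 9-week 1% in 342 genes, from 10% in 2388 and from 0.1% in 1952. In a contrast chosen after the data were seen, both 1% groups together differed from the 9-week 0.1% and 10% groups in 4390 of 16516 genes, with 2482 higher and 1908 lower at 1%. The genes that rose held 9.81% ± 1.73 of counts at 9 weeks and 1%, 11.1% ± 1.2 at 27 weeks and 1%, 5.22% ± 0.84 at 0.1% and 4.56% ± 0.47 at 10% (SD, n = 5 each). Nfu_g_1_018107 was at 14.7 ± 9.3 CPM at 9 weeks and 1% and 9.85 ± 8.76 CPM at 27 weeks, against 0.220 ± 0.123 CPM at 0.1% and 0.334 ± 0.119 CPM at 10%, a log2 change of 5.46 ± 0.50 (SE; edgeR adjusted p = 2.67e-07). Nfu_g_1_001720 was at 23.2 ± 12.5 and 26.0 ± 15.7 CPM in these 1% groups, against 0.772 ± 0.744 CPM at 0.1% and 0.439 ± 0.132 CPM at 10%, a log2 change of 5.42 ± 0.47 (SE; edgeR adjusted p = 2.13e-07). Both genes were higher in 10 of 10 libraries at 1% than in any of the 10 others. Nfu_g_1_020030 was lower at 1% (62.6 ± 69.3 CPM at 9 weeks and 3.74 ± 1.23 CPM at 27 weeks) than at 0.1% (547 ± 514 CPM) and 10% (724 ± 278 CPM), a log2 change of -5.36 ± 0.76 (SE; edgeR adjusted p = 2.77e-05), in 8 of 10 libraries below all others. Nfu_g_1_021215 was at 34.9 ± 48.7 and 30.9 ± 21.5 CPM in the 1% groups, against 749 ± 650 CPM at 0.1% and 709 ± 375 CPM at 10%, a log2 change of -4.47 ± 0.83 (SE; edgeR adjusted p = 0.000420), in 7 of 10 libraries below all others. Its log2 change was -5.10 without replicate 3 at 9 weeks and 1%. Age and dose are not balanced in this contrast, since 27-week fish were sampled only at 1%.

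**Figure D3:**
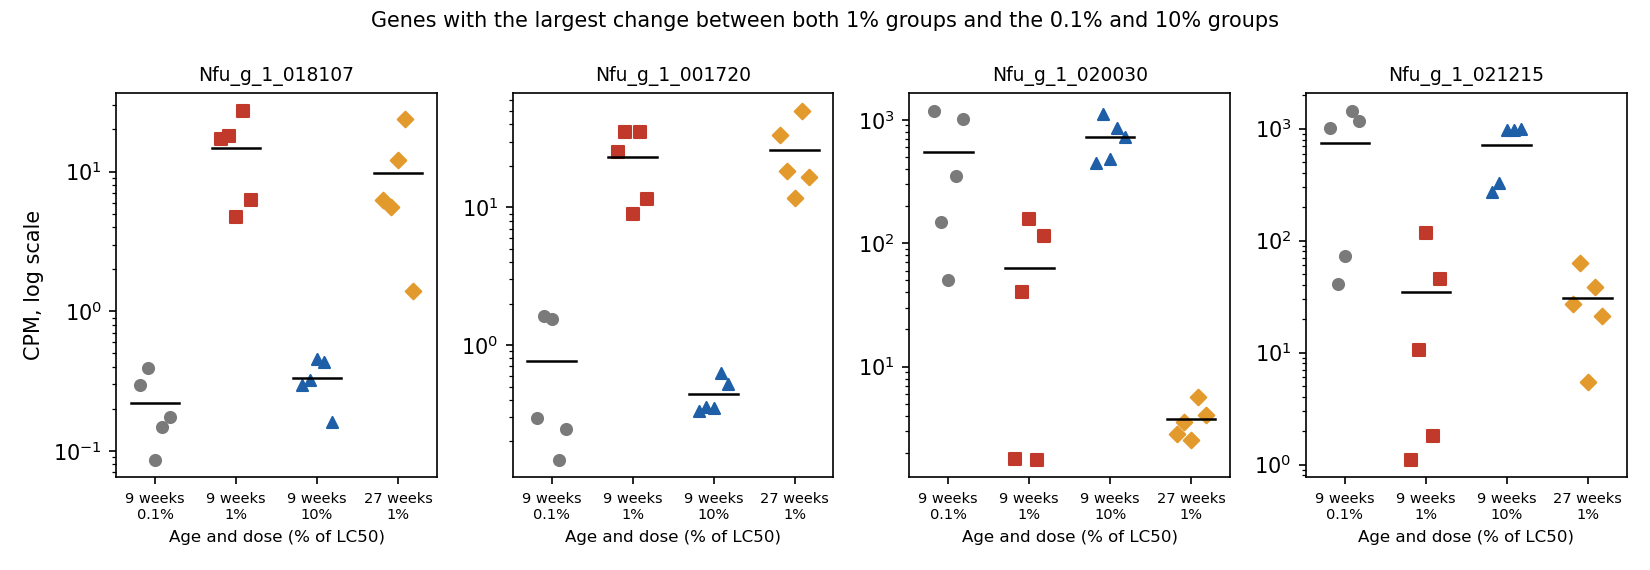
CPM on a log scale (y axis) of the 2 genes with the largest rise and the 2 with the largest fall between both 1% groups and the 9-week 0.1% and 10% groups, by age and dose (x axis); points are libraries, 5 per group, and lines are group means. In Nfu_g_1_018107 and Nfu_g_1_001720 all 10 libraries at 1% lie above the other 10.

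In 713 of 16516 genes the ranges of the 10 libraries at 1% and of the 10 libraries at other doses did not overlap. For exchangeable libraries and a division fixed beforehand, chance would give 0.179 genes. This division was chosen after the data were seen, so that value is not its chance level. Of the 713 genes, 481 were higher and 232 lower at 1%. Pairing the 9-week 1% group with 0.1% gave 0 such genes, and pairing it with 10% gave 6. The fold changes of the 9-week and of the 27-week 1% group against the other doses, each taken against its own 5 of the 10 libraries, correlated across genes with a mean r of 0.447 over 252 divisions (0.257 to 0.604). Undivided, r was 0.560, against a mean of 0.386 (-0.283 to 0.901) for simulated groups with no effects, and so lay within the simulated range. The covariance was 0.304 against 0.0649.

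Whether the step from 1% to 10% moved genes along or against the difference with age was asked across all genes tested. Both comparisons subtract the 9-week 1% group, which lay apart from all others on principal component 1. Dividing its libraries removes noise shared by both comparisons, but not a deviation of that group as a whole. Such a deviation would move genes the same way in both. The values below therefore cannot tell it from a step in dose that runs along age. The fold changes of 10% against 1% and of 27 against 9 weeks correlated with a mean r of 0.218 over 20 divisions of the shared 9-week 1% libraries (0.035 to 0.352). Undivided, r was 0.543, against a mean of 0.494 (-0.496 to 0.898) for simulated groups with no effects, and the covariance was 0.314 against 0.0925. The undivided r lay within the simulated range. With division, the mean r was 0.317 without replicate 5 and 0.136 without replicate 4 at 9 weeks and 1%. Of the called genes, 98 rose and 90 fell in both comparisons, where independent lists would share 20.1 and 33.7. With the 9-week 1% libraries divided, the medians were 13 (0 to 134) and 17.5 (0 to 343), where independent lists would share 3.40 and 10.5. Opposite directions were seen in 9 and 12 genes, against 23.6 and 28.7 for independent lists. With the libraries divided, these medians were 5 (0 to 146) and 5 (0 to 109), against 5.21 and 8.04 for independent lists, so little of that deficit remained.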

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

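The tests of a label swap, of single libraries, of abundant genes, of transcript length across groups, of the separate tables, of the joint deviation of both 1% groups and of the score tables were chosen after the result was seen. Those of length, other tissue and rare transcripts in replicate 5, and the divisions of the libraries, were written before their values were computed. The rare-transcript test was nevertheless built on gene counts already seen, and the contrasts of the 1% groups were themselves chosen after seeing the data.

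The verdict rules of 2 tests were changed after their values were seen. As first written, both values, 0 genes for RNA of another tissue and 7.93 CPM for few starting molecules, would have counted against the explanation. The first rule was changed because the count was 0 in every library, so the measure had no power. The second was changed because genes at low levels cannot show a 4-fold drop, so that all tested genes were an unfair background.

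In 61 groups of 5 values tested for a value far from the others, 4 stood out, where chance gives about 1 in 20, or 3.05 of 61, so the number is near chance. Replicate 5 of the 9-week 1% group had a median correlation with its group of 0.827, where the other 4 lay between 0.935 and 0.954. Replicate 3 of the 27-week group had a median correlation of 0.944, below the 0.958 to 0.959 of the other 4. Replicate 5 of the 27-week group was sequenced to 33.7 M counts, above the 23.5 M to 25.5 M of the other 4. Nfu_g_1_007386 was at 4.54 CPM in replicate 3 of the 9-week 1% group and between 243 and 857 CPM in the other 4.

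Replicate 5 of the 9-week 1% group deviated broadly, by a median of 0.92 log2 units over tested genes against 0.22 to 0.50 in the other 19 libraries, and 1035 genes (median count 9) were at least 4-fold lower in it than in each of these, where no other library had more than 11. A swapped label was argued against, by a narrow margin, since its highest correlation was with its own group (0.849, against 0.835 with any other group). Its correlations with its own group reached down to 0.821. On principal component 1 it lay at -45.9, among its own group. A length trend over all genes stays open. The rank correlation of its deviation with gene length (-0.118) was smaller in size than the largest elsewhere (0.141). By the rule written before, this counts against a trend. But the 0.141 was positive, in replicate 2 at 10%, and -0.118 was the most negative value, the next being -0.102. A rank correlation also ignores the size of the deviations. The negative sign means that longer genes tended to be lower in replicate 5. The 1035 lower genes were instead shorter, with a median length of 1986 nt against 2587 nt for all tested genes. Both measures thus point in opposite directions. Genes at least 4-fold higher in replicate 5 than in each other library numbered 19. Replicate 3 at 27 weeks had 84 such genes, and each remaining library at most 13. No test was built on that count. The measure used for RNA of another tissue was genes at 10 CPM or more in replicate 5 and under 0.5 CPM in all 15 libraries of other groups. RNA of another tissue stays open, because this measure gave 0 genes in this and in every other library. So does a difference of the fish itself, which was not tested, and the loss of rare transcripts through few starting molecules stays open, because the median level of the 1035 genes elsewhere (7.93 CPM) lay between that of all tested genes (6.84 CPM) and that of the genes able to show such a drop (9.48 CPM).

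That both 1% groups differed from 0.1% and 10% was not explained by the separate table of the 0.1% group, since 10% and 0.1%, which lie in different tables, differed in 8 genes, while 10% and 1%, which share a table, differed in 3713. Nor did it rest on replicate 5 of the 9-week 1% group, on abundant genes or on a length trend: the 4390 genes became 5359, 4369 and 4417 without that replicate, without the 100 most abundant genes and with a length trend removed per library. What stays open is a response peculiar to 1%, against a shared circumstance of the 1% fish such as handling, collection time or origin. Both predict that the 9-week and 27-week 1% groups deviate together (mean r 0.447, lowest 0.257), no label parts them, and they cannot be told apart. A response to dose with its extreme at 1% may therefore be only apparent.

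The tables labelled RPKM are consistent with library totals recycled down the rows instead of across the columns, since the divisors equalled the library totals within a relative difference of 3.64e-06. No biological explanation applies to this pattern.

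The rule written before asked for fewer than 5 of 100 divisions reaching the real count. By it, chance division of the libraries was argued against for the comparisons planned beforehand, except 10% against 0.1%. For 10% against 1%, 1 division, the real one, gave 3713 genes and the highest other 477. For 27 against 9 weeks the values were 461 and 2, for 1% against 0.1% 3204 and 1341, for 1% against the mean of 0.1% and 10% 4484 and 1137, and for both 1% groups against the others 4390 and 2, with the real division alone (1) reaching its count in each. For the last 2 contrasts, chosen after seeing the data, the divisions do not allow for that choice, so chance is not taken as excluded. Their divisions mix libraries of different groups, so they cannot tell which groups belong together. For 10% against 0.1%, 2 of 100 divisions gave 8 genes or more. Of these 1 was the real division, and the other gave 428 after exchanging replicate 3 at 10% with replicate 4 at 0.1%, many times the real 8. Why that division gave so many genes was not tested. Although 2 of 100 meets the rule, chance division is therefore not taken as excluded there.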

How the results depend on the processing

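The contrasts with both other doses, their correlations, the rescaled values, the removed length trend, the omission of 100 abundant genes and that of a 9-week 1% library from the comparison of 10% with 0.1% were chosen after seeing the data. No paired analysis was possible because the labels name no pairs and the replicate numbers only name libraries. Planned tests of gene lists, and a covariate from pancreas markers, were not run as no identifier matched a name. The cause of the differences below was not tested, except that a test against 1.5-fold is stricter by construction. Smaller sets of libraries or genes leave less information, but this need not explain the drops. Without replicate 5 of the 9-week 1% group, 4923 genes passed for 10% against 1% and 5359 for both 1% groups, more than in the full fits. No named gene reversed direction. The balance of higher and lower calls was not stable for age (46.0% higher; 33.9% to 84.0% across settings) nor for the few calls of 10% against 0.1%; it held in the other comparisons. Counts of genes stayed within 1.5 times under DESeq2 size factors, without a filter, with a CPM of 1 in 5 libraries, without the 100 most abundant genes and with the length trend removed. Tested against 1.5-fold, 1219 genes passed for 10% against 1%, 23 for 27 against 9 weeks, 997 for 1% against 0.1%, 2 for 10% against 0.1%, 1366 for 1% against the mean of the other doses and 1196 for both 1% groups against the others. With only the groups compared in the fit, 2453, 25 and 1091 genes passed for the first 3 of these, the 25 being 84.0% higher calls. DESeq2 called 1785 genes for age and 144 for 10% against 0.1%, and limma voom 225 and 5. On the deposited score tables, 1747 and 1763 genes passed for 10% against 1% and 33 and 51 for age (pseudocounts 0.1 and 1); after rescaling, 2808 and 151 passed. Leaving out 1 library gave 2780 to 4923 genes for 10% against 1%, 46 to 626 for age, 2277 to 3439 for 1% against 0.1%, 3 to 37 for 10% against 0.1%, 3581 to 4538 for 1% against the mean of the other doses and 3902 to 5359 for both 1% groups. The correlation of dose and age changes ranged from 0.136 to 0.317, lowest without replicate 4 and highest without replicate 5 at 9 weeks and 1%; that of both 1% groups from 0.406 to 0.464; and that of 0.1% and 10% from 0.416 to 0.585. Without dividing the shared libraries these were 0.543, 0.560 and 0.839, inflated by construction. For single genes under alternatives, 460 values stayed past the threshold and 75 did not; 13 more gave no value, as the gene was not tested (11) or got no adjusted p (2, by DESeq2).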

Other observations

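Both hypotheses about neighbouring rows were fixed before their result was seen; the counts of genes peculiar to 1 library were chosen afterwards.

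Replicate 3 of the 27-week group held 84 genes at least 4-fold higher than in each of the other 19 libraries, where no other library had more than 19. Of these 84 genes, 8 were among the 212 called higher at 27 weeks. The same library held most of the counts of Nfu_g_1_014761 and Nfu_g_1_022891.

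Nfu_g_1_007386 was high in 4 of the 20 libraries, all of the 9-week 1% group, between 243 and 857 CPM, and stood between 0.64 and 10.1 CPM in the other 16. Nfu_g_1_007647, lower at 10% than at 0.1%, stood at 113 ± 61 CPM at 9 weeks and 1% and at 1254 ± 332 CPM at 27 weeks and 1% (SD, n = 5 each).

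It was asked whether genes that change together sit in neighbouring rows of the tables, whose relation to genome order was not checked. For both 1% groups against the other doses, 709 pairs of adjacent tested rows were called in the same direction, where 1000 random row orders gave a mean of 413 and at most 475. Pairs called in opposite directions numbered 339, against a mean of 399 in random orders. For 27 against 9 weeks, 14 pairs were called in the same direction, against a mean of 4.56 and at most 13, a narrow margin. Pairs called in opposite directions numbered 7 there, against a mean of 4.56. Neighbouring rows may therefore change together, but parts of 1 gene under 2 identifiers, duplicated genes that share reads and regional regulation would all give this, and none was tested.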
